A study of Mus musculus with 6 samples.

How the data were processed

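RNA of bone-marrow-derived macrophages from wild-type (control) and factor H knockout (FHKO) mice was measured in 3 libraries per group. Groups and replicate numbers were taken from the sample titles, with the genotype field as a second label. Other mouse strains that the labels' protocols mention were not analysed here. The platform, the software and its versions were not given in the sources used here. The deposited table held 753 gene rows, each with 1 symbol, and 14 control rows, 8 named as negative and 6 as positive controls, the layout of a probe-counting panel.

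The deposited values are a normalised signal: by the values themselves, each gene's value is a whole-number count multiplied by 1 factor per library. The factor was recovered from the values as the step of which they are multiples, and 99.7% of all gene values were whole multiples within a tolerance of 0.0051, the rounding of the table. A few values stood at exactly 1, which looks like a floor (0 to 3 per library). The control rows were whole numbers and had not been multiplied by that factor. The geometric mean of 16 of the 20 reference genes on the panel was equal in the 6 libraries (SD of 6.82e-06 on the log2 scale). No other choice of 16 of them came closer than 0.00282. The authors' factors therefore set these 16 genes equal, as read from the values and not from any protocol. The 4 not used were G6pdx, Gusb, Sdha and Tubb5. Among the 16, Hprt varied most, by 1.38 on the log2 scale between libraries. This choice fixes what counts as no change. Negative-control rows averaged 8.38 to 14.8 counts per library, so genes near a normalised count of 20 are close to background.

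The main test was set before the data were examined. Genes at a normalised count of 20 or more in at least 3 of the 6 libraries were kept (490 genes), log2(value + 1) was fitted with limma 3.58.1 (lmFit, and eBayes with an intensity trend) in R 4.3.3, and p-values were two-sided and adjusted by the Benjamini-Hochberg method at 0.05. No block or covariate was used. Log2 differences are FHKO minus control on the log2(value + 1) scale, which understates the change of low genes. Gene lists fixed in advance were tested with camera (preset correlation of 0.01), adjusted over the 34 lists with at least 3 tested members, and again with an estimated correlation, with ranks and with fry. Counts adjusted over the list alone used the members' p-values only. Symbols were checked against the mouse gene table of assembly GRCm38.p6: 743 matched directly, 9 through a synonym and 1 did not match. No coordinates were used.

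The genes named were set by a rule made in advance: C3ar1, Ccr2 and Cx3cr1 always (Trpm7 also belonged to the rule and was not analysed here), then up to 12 genes per direction past the threshold with separate groups. Where fewer passed, the genes of smallest unadjusted p with separate groups were added until 6 were named per direction. For each list described, the 3 members of smallest p were named, and 4 for the Fc receptor list. Some items that these rules and the plan set are not reported here. Which 20 of the 34 tested lists to describe, and the naming of Adgre1, was decided after values had been seen.

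Alternatives were the replicate number as a block, leaving out each library, other scalings, quantile normalisation, other filters, pseudocounts of 5 and 20, other eBayes settings, an adjusted p under 0.1 and a minimum of 1.5-fold. Added after seeing the data were edgeR 4.0.16 (quasi-likelihood test with TMM) and DESeq2 1.42.0 on the recovered counts, scaling without Hprt, a filter at each library's negative-control mean plus 2 SD, and the score of an axis of variation within the groups as a covariate. All replicate pairs differed by more than sampling noise (chi-square per degree of freedom of 9.02 to 33.0 within groups), so each library was counted as 1 replicate.

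The procedure was tested on simulated data for this comparison, with 200 of the 490 genes changed in 20 runs. limma recovered 55.8% of genes changed 1.5-fold, 87.2% of those changed 2-fold and 98.0% of those changed 4-fold. Of its calls 3.28% were unchanged genes, and 3 of 20 runs without changed genes had any call. The simulated noise was independent between genes, whereas 56.6% of the real variance within groups lay on a shared axis. These rates therefore describe the procedure and are not the power or error rate in these data. Figures were drawn with matplotlib 3.10.9.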

Results

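RNA levels of 753 genes, most of them genes of innate immunity and of the myeloid lineage, were measured in macrophages grown from mouse bone marrow. Factor H is a soluble regulator of the complement system, a cascade of plasma and locally made proteins that marks and attacks targets. Macrophages of factor H knockout mice (FHKO, n = 3) were set beside macrophages of wild-type mice (control, n = 3), and this is the one comparison that the labels give. By its title, the series concerns how factor H keeps macrophages in their resting state, with the ion channel TRPM7 as the pathway. The values recovered as whole counts summed to 725234, 996065 and 1083624 in control libraries 1 to 3 and to 717503, 1348064 and 925070 in FHKO libraries 1 to 3. The aspartic protease gene Ctsd took 12.1% to 17.7% of each sum. Of the 753 genes, 490 reached a normalised count of 20 in at least 3 of the 6 libraries and were tested. Trpm7 was not analysed here, and the genotype labels were not checked against expression.

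The comparison asked which of these genes differ in macrophages that lack factor H. Il1rn, which encodes the secreted antagonist of the interleukin-1 receptor, fell in the knockout cells. Its normalised count was 909 ± 49.9 (SD, n = 3) in control and 535 ± 4.06 (SD, n = 3) in FHKO macrophages, and the 3 FHKO values lay below the 3 control values. That FHKO spread is smaller than the sampling noise of such counts, so it understates the uncertainty. The same holds for several spreads below, among them the control spreads of Nlrp3, Id1 and Id3 and those of Mmp19 and Kcnq1ot1 in both groups. The difference of Il1rn was -0.76 on the log2 scale with a standard error of 0.087 (limma, adjusted p = 0.020). It was the only gene past an adjusted p of 0.05 in limma, with 1 gene lower and 0 higher. At an unadjusted p under 0.05 there were 93 genes higher and 17 lower, 110 in all. Chance would give 24.5 if genes varied independently, and the highest of the other splits of the 6 libraries, control 1, control 2 and FHKO 1 against the rest, gave 78. edgeR on the recovered counts also called 1 gene, Il1rn, and DESeq2 called 33, with 19 higher and 14 lower. Leaving out any 1 library other than FHKO 2 ended the call of Il1rn, with limma's adjusted p between 0.0632 and 0.169 and a log2 difference between -0.72 and -0.79.

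**Figure D1:**
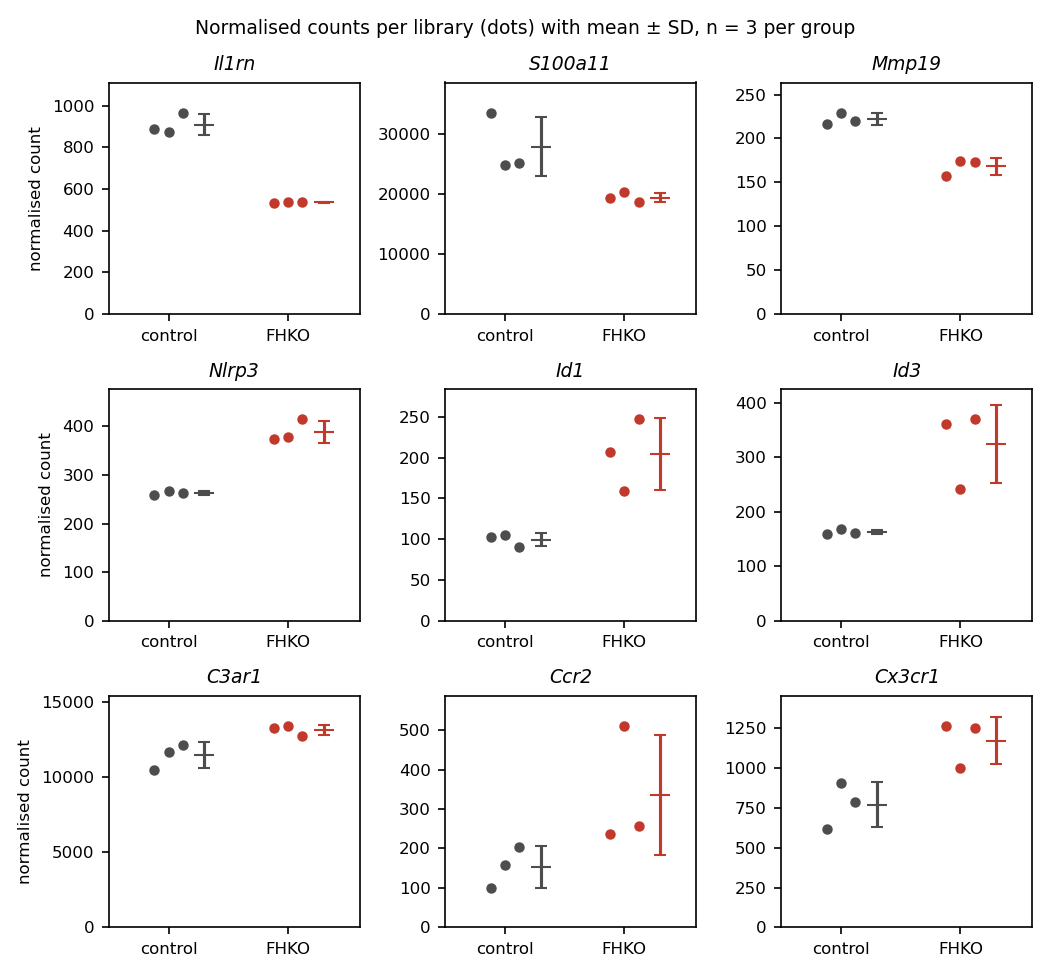
Normalised counts of 9 named genes in each library (dots, vertical axes from 0), with the group mean and SD beside them, for 3 control and 3 FHKO libraries. The FHKO values of Il1rn lie near 535 and the control values near 909, while the groups of Ccr2 and Id3 have a wider spread among FHKO libraries.

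The values were scaled by a set of reference genes, and relative to those genes most of the panel was slightly higher in FHKO macrophages. The median log2 difference of the 490 genes was 0.16, and 71.8% of them lay above 0. With library medians set equal instead, every log2 difference was lower by 0.29 and the median gene moved to -0.14. That scaling makes positive differences smaller and negative ones larger for all genes below, also where its value is not given. With that scaling limma called 14 genes, 4 higher and 10 lower, and relative to the median gene the deposited scaling put Il1rn at -0.92. In 143 genes (29.2%) the 3 FHKO values did not overlap the 3 control values, 112 of them higher and 31 lower. Random labels give 10% on average, but the genes did not vary independently. The first principal component of the tested genes held 62.0% of the variance and placed all 3 controls below all 3 FHKO libraries. A shared axis alone could therefore raise this share.

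**Figure D2:**
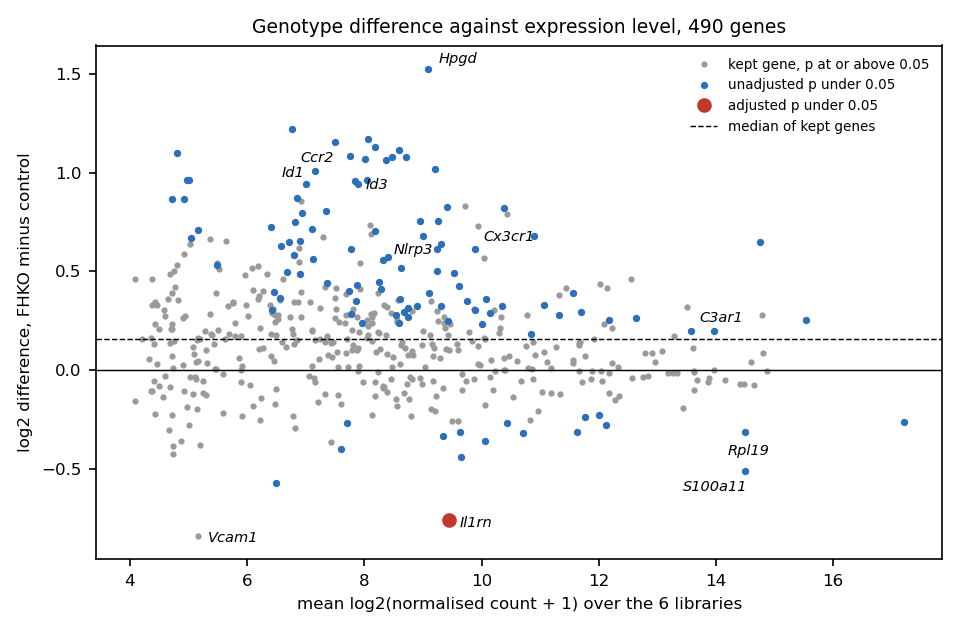
Log2 difference between FHKO and control macrophages (vertical axis) against the mean log2 normalised count over the 6 libraries (horizontal axis) for the 490 genes tested. Il1rn is the single gene past the adjusted threshold, and the dashed line marks the median gene at 0.16.

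Several genes with separate groups missed the threshold. Nlrp3, the sensor protein of an inflammasome that processes interleukin-1 beta, had a normalised count of 263 ± 4.45 (SD, n = 3) in control and 389 ± 22.3 (SD, n = 3) in FHKO macrophages, a log2 difference of 0.56 with a standard error of 0.097 (limma, adjusted p = 0.0993). It fell to 0.26 with library medians set equal and to 0.28 after quantile normalisation (limma, adjusted p = 0.262 and 0.297). Id1 and Id3 encode helix-loop-helix proteins that lack a DNA-binding domain and block other transcription factors. Id1 was at 99.6 ± 7.99 in control and 204 ± 44.1 in FHKO (SD, n = 3), and Id3 at 163 ± 4.05 and 324 ± 71.1. Their log2 differences were 1.01 and 0.96, each with a limma adjusted p of 0.0993 and a DESeq2 adjusted p of 0.00732, and with library medians set equal they were 0.72 and 0.67. Without FHKO library 2 both passed, with log2 differences of 1.18 and 1.16 and limma adjusted p of 0.0202 and 0.00945. Without any other 1 library both missed (limma, adjusted p of 0.0904 to 0.339). After quantile normalisation they had 0.65 and 0.71 (limma, adjusted p = 0.210 and 0.208), and edgeR called neither (adjusted p = 0.0909 for each). Next by p came Slc16a6 of the monocarboxylate transporter family (log2 difference 0.87), the long non-coding RNA Kcnq1ot1 (0.87) and Hpgd, which encodes the enzyme that inactivates prostaglandins (1.53), each at a limma adjusted p of 0.138. With library medians set equal they had 0.58, 0.57 and 1.23, and Hpgd passed (limma, adjusted p = 0.028). DESeq2 called Slc16a6 and Hpgd (adjusted p of 0.00938 and 0.000752) and gave Kcnq1ot1 no adjusted p, while edgeR called none of them (adjusted p of 0.0909 to 0.114). Kcnq1ot1 was at 18.7 ± 2.98 in control and 34.7 ± 2.30 in FHKO macrophages (SD, n = 3), so its control values lay close to background. Its log2 difference fell to 0.50 with a pseudocount of 20. The strand of the Kcnq1ot1 probe relative to the gene Kcnq1, which it overlaps, was not given in the sources used here. Hpgd differed most in fold of these, from 342 ± 144 to 936 ± 197 (SD, n = 3).

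On the lower side, the genes closest to the threshold after Il1rn were S100a11, a calcium-binding protein gene, Mmp19, a matrix metalloproteinase gene, and Rpl19. Rpl19 is a ribosomal protein gene and was among the genes used for the scaling. S100a11 was at 27838 ± 4891 in control and 19382 ± 786 in FHKO macrophages (SD, n = 3), with a log2 difference of -0.51. Mmp19 was at 222 ± 6.60 and 168 ± 9.46, with a log2 difference of -0.40, and Rpl19 had -0.31. Hbegf, a growth factor gene, and Fcgr4, an activating receptor for IgG, had -0.57 and -0.33. The limma adjusted p of these 5 genes lay between 0.138 and 0.148, and DESeq2 called all 5 (adjusted p of 0.00365 to 0.0446). By edgeR none of them passed (adjusted p of 0.0909 to 0.109). With library medians set equal, S100a11, Mmp19, Hbegf and Fcgr4 were among the 14 genes called.

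The receptors behind other mouse strains that the labels mention were chosen before the data were examined. C3ar1, the receptor of the complement fragment C3a, was at 11441 ± 856 in control and 13124 ± 334 in FHKO macrophages (SD, n = 3), a log2 difference of 0.20 (limma, adjusted p = 0.194) that turned to -0.09 with library medians set equal. Ccr2, the receptor of monocyte chemoattractant chemokines, was at 154 ± 53.0 and 335 ± 152 (SD, n = 3), a log2 difference of 1.09 (limma, adjusted p = 0.148). Cx3cr1, the fractalkine receptor, was at 771 ± 143 and 1172 ± 148 (SD, n = 3), a log2 difference of 0.61 (limma, adjusted p = 0.138). With library medians set equal Ccr2 had 0.79 and Cx3cr1 0.32. None of the 3 passed limma's threshold, and Ccr2 was among the 33 genes called by DESeq2 (adjusted p = 0.0311) but missed in edgeR (adjusted p = 0.150).

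Of 44 gene lists fixed before the data were examined, 34 had at least 3 tested members. Counts of members that passed are limma's with the deposited scaling, and members called by DESeq2 or with library medians set equal are named beside them. Those settings called the most genes of those used. By edgeR on the same counts, quantile normalisation or scaling by all reference genes, Il1rn was the only list member called. DESeq2 gave no adjusted p to some low genes, among them Mx1, Cxcl10, Mx2, Cxcl2, Ccl12, Irf4, H2-Ob, Vegfc and Fscn1. Genes of Fc receptors and of the ITAM signalling that follows them stood lower than the other genes as a list, with a mean of -0.21 relative to the median gene (camera of limma with a preset correlation, adjusted p = 0.0465). With an estimated correlation the list had an adjusted p = 0.972. The list's mean log2 difference itself was -0.05, so its place relative to the median gene comes largely from the shift of the panel. Of its 10 tested members, 5 lay above 0 and 9 below the median gene. On their own 0 passed limma's threshold, over all genes or adjusted over the list alone. At an unadjusted p under 0.05, 3 were lower and 0 higher. DESeq2 called 3 of them lower, Fcgr3, Fcgr4 and Lat2, and limma with library medians set equal called Fcgr3 and Fcgr4. Fcgr3, an activating IgG receptor, was at 4427 ± 74.5 in control and 3779 ± 204 in FHKO macrophages (SD, n = 3), a log2 difference of -0.23. Lat2, an adaptor of these receptors, had -0.24, Fcgr4 had -0.33 and Trem2, a receptor that signals through the ITAM adaptor Tyrobp, had -0.19. The list of reference genes also stood lower, by -0.18 relative to the median gene (camera, adjusted p = 0.0465, and adjusted p = 0.972 with an estimated correlation). Of its 20 members 16 are the genes that the scaling set equal, so its mean log2 difference is near 0 by construction (-0.02). Its place below the median gene therefore restates the shift of the panel and is not a separate finding. Its call was lost with library medians set equal (camera, adjusted p = 0.0703). Rpl19, Alas1 and Eef1g, all among the scaling genes, had log2 differences of -0.31, -0.36 and -0.32. DESeq2 called Alas1 and Rpl19, and limma with library medians set equal called Alas1. No list passed with library medians set equal, with an estimated correlation, with ranks or with fry. Leaving out any 1 library ended the call of the Fc receptor list, and so did the replicate block.

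Among inflammatory genes, the inflammasome list had 5 tested members, all above 0 and 4 above the median gene, and the list did not pass (camera, adjusted p = 0.566). Nlrp3 was the 1 member past the threshold adjusted over the list alone, and Il18 and Casp1 had log2 differences of 0.49 and 0.30, or 0.19 and 0.01 with library medians set equal. The list of pro-inflammatory cytokines and mediators had 10 tested members, with 0 past either threshold (camera, adjusted p = 0.837). Its median stood 0.02 above the median gene and its mean 0.03 below it (-0.03), the direction of the test. Il15 had a log2 difference of 0.46 and S100a8 had -0.29, and Tnf had 0.19, which turned to -0.11 with library medians set equal and to -0.08 after quantile normalisation. Of 11 NF-kB pathway genes, 10 lay above 0 and 7 above the median gene (camera, adjusted p = 0.811). Nfkbiz, Nfkb1 and Nfkbia had log2 differences of 0.48, 0.32 and 0.28, or 0.19, 0.03 and -0.01 with library medians set equal. Of 16 genes of Toll-like receptor signalling, 11 lay above the median gene (camera, adjusted p = 0.837). Tlr4, the lipopolysaccharide receptor, had 1.08 with FHKO values spread from 395 to 842, and Tlr9 and Cd180 had 0.31 and 0.23, or 0.01 and -0.06 with library medians set equal. Of 7 interferon-stimulated genes 4 lay above the median gene (camera, adjusted p = 0.837), with Mx1 at 1.10, Cxcl10 at 0.51 and Mx2 at 0.39, or 0.81, 0.22 and 0.09 with library medians set equal. Mx1 and Mx2 averaged 19.4 and 22.4 in control, close to background, so the size of their differences is uncertain. None of the members of the NF-kB, Toll-like receptor and interferon lists passed limma's threshold over all genes or adjusted over the list alone. DESeq2 called 1 of them, Tlr4, and gave Mx1, Cxcl10 and Mx2 no adjusted p.

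The list of alternative activation, genes linked to interleukin-4 or to resolving macrophages, had 16 tested members, of which 4 lay above the median gene (camera, adjusted p = 0.388). Il1rn passed over all genes, and adjusted over the list alone 2 members passed, Il1rn lower and the transcription factor gene Klf4 higher (log2 difference 0.81). DESeq2 called both over all genes. Irf4, a transcription factor gene, had 0.53. Chemokines had 14 tested members (camera, adjusted p = 0.878), with Cxcl2 at 0.36 and Ccl12 at 0.49 (0.07 and 0.19 with library medians set equal) and Cxcl10 as above, and 0 passed limma's threshold. Ccl12 averaged 21.1 in control, close to background. Of 9 chemokine receptors 6 lay above the median gene (camera, adjusted p = 0.911). Cx3cr1 and Ccr2, given above, were among them, and 0 members passed limma's threshold, while DESeq2 called Ccr2.

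None of the tested complement components or receptors passed limma's threshold, and DESeq2 called 0 of them. Of 6 complement components and regulators on the panel 4 were tested, and 0 lay above the median gene (camera, adjusted p = 0.827). C1qb, a chain of the initiating protein C1q, was at 18647 ± 1703 in control and 18009 ± 1092 in FHKO macrophages (SD, n = 3). C1qa had a log2 difference of 0.14, or -0.15 with library medians set equal, and C3, the central component, had 0.02, which turned to between -0.30 and -0.11 under median scaling, quantile normalisation, edgeR and DESeq2. Of 6 complement receptors 1, C3ar1, lay above the median gene (camera, adjusted p = 0.388), and Itgax and Itgam, the alpha chains of complement receptors that bind C3 fragments, had -0.26 and 0.16, the second turning to -0.14 with library medians set equal. The list of MHC class II presentation had 12 tested members, with 4 above the median gene and 0 past the threshold (camera, adjusted p = 0.811). Cd40, H2-Ob and Ctss had log2 differences of 0.33, 0.31 and 0.28, or 0.04, 0.01 and -0.02 with library medians set equal. H2-Ob averaged 20.7 in control, close to background.

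**Figure D3:**
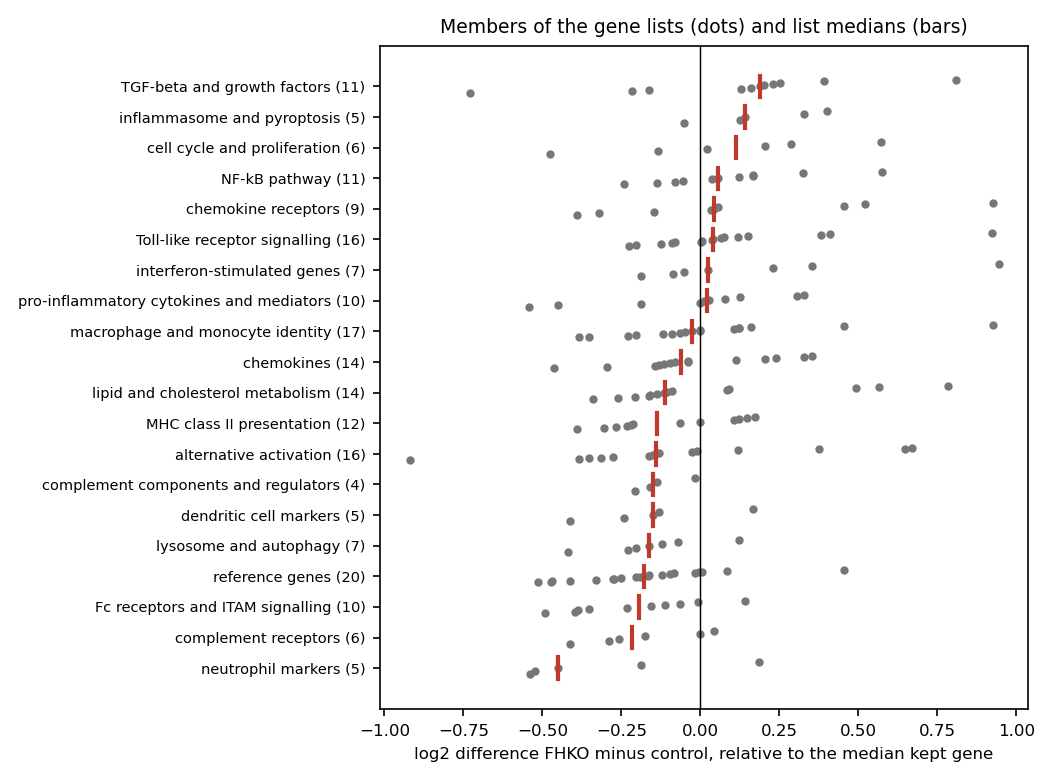
Log2 difference between FHKO and control macrophages relative to the median gene (horizontal axis) of each tested member (dots) of 20 gene lists, with the list median (bars) and the number of tested members in parentheses. The list of Fc receptors and ITAM signalling has 9 of its 10 members below the median gene (0 on this axis), and Il1rn is the lowest member of the alternative activation list.

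Growth factor and cell cycle genes held members that passed limma's threshold adjusted over the list alone and missed it over all genes. Of 11 genes of TGF-beta and growth factors 8 lay above the median gene (camera, adjusted p = 0.811). Adjusted over the list alone 3 passed, Vegfc (log2 difference 0.97) and Pdgfb (0.39) higher and Hbegf (-0.57) lower. With library medians set equal Vegfc had 0.67 and Pdgfb 0.09. Vegfc averaged 22.5 in control, close to background, so the size of its difference is uncertain. Of 6 cell cycle genes 4 lay above the median gene (camera, adjusted p = 0.878). Adjusted over the list alone 3 passed, the mitotic genes Birc5 (0.45) and Ccnb2 (0.36) higher and Cdkn1a, an inhibitor of cyclin-dependent kinases, lower (-0.32). With library medians set equal Birc5 had 0.15 and Ccnb2 0.07. Of 14 lipid and cholesterol genes 5 lay above the median gene, with a median of -0.11 relative to it, the direction of the test, and a mean of 0.03 (camera, adjusted p = 0.878). Ptgs1, which encodes a cyclooxygenase, passed adjusted over the list alone with a log2 difference of 0.72, and Lpl and Fabp4 had 0.65 and 0.94. Of 7 lysosome and autophagy genes 1 lay above the median gene (camera, adjusted p = 0.388). Ctsd was at 165563 ± 18776 in control and 137489 ± 1562 in FHKO macrophages (SD, n = 3), a log2 difference of -0.26. Ctss had 0.28 and Grn had 0.09, and Grn turned to between -0.21 and -0.04 under median scaling, edgeR and DESeq2. Over all genes 0 members of these 4 lists passed limma's threshold. DESeq2 called Hbegf, Cdkn1a and Ctsd, each lower, and limma with library medians set equal called Hbegf and Cdkn1a.

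Of 19 genes of macrophage and monocyte identity on the panel 17 were tested, and 6 of these lay above the median gene, and the list's median of -0.03 relative to it and its mean of 0.02 differed in sign (camera upward, adjusted p = 0.962). None passed limma's threshold, and DESeq2 called 1, Ccr2. Adgre1, the gene of the macrophage marker F4/80, was at 12079 ± 404 in control and 13040 ± 114 in FHKO macrophages (SD, n = 3), a log2 difference of 0.11 that turned to -0.18 with library medians set equal. Csf1r, the receptor of the growth factor that sustains macrophages, was at 5812 ± 202 and 6986 ± 371 (SD, n = 3), a log2 difference of 0.26 that turned to -0.03 with library medians set equal. Markers of other cell types were mostly low. None of the 3 NK cell and none of the 3 B cell genes on the panel reached the level for testing, and 2 of 6 T cell genes, 5 of 12 neutrophil genes and 5 of 9 dendritic cell genes did. The neutrophil list stood lower by a median of -0.45 relative to the median gene, with 0 members passing (camera, adjusted p = 0.225, and adjusted p = 0.972 with an estimated correlation). S100a8 was at 124 ± 12.4 and 102 ± 12.1 (SD, n = 3), Mmp9 had a log2 difference of -0.37, and Csf3r had 0.34, or 0.05 with library medians set equal and -0.02 after quantile normalisation. Among dendritic cell genes (camera, adjusted p = 0.773), Cd83 had 0.32 (0.03 with library medians set equal), Itgax had -0.26 and Fscn1 had -0.08, and 0 passed limma's threshold.

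With 3 libraries against 3, an exact permutation test of one gene cannot give a two-sided p under 0.1, and the calls rest on limma's estimate of the spread across genes. Nothing in the labels says that the replicates came from separate animals or cultures, so the p-values measure the spread between these libraries, which may be technical.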

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

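The tests with edgeR, DESeq2, scaling without Hprt, the negative-control filter, the axis score and quantile normalisation of the lists were chosen after the data were seen. Il1rn was lower in all 21 alternative settings run, with a log2 difference between -0.72 and -1.06, and passed an adjusted p of 0.05 in 14 of the 20 other than the axis score (limma without a trend gave 0.04997). It missed with the replicate block (0.0991) and without each library except FHKO 2 (up to 0.169). The count of genes past the threshold (1) was 0 with the replicate block and 0 to 3 when 1 library was left out: 0 without control 1, 2 or 3 or FHKO 1 or 3, and 3 without FHKO 2 (Id1, Id3 and Il1rn). It was 14 with library medians set equal (4 higher, 10 lower), 4 at an adjusted p under 0.1 and 33 with DESeq2 (19 higher, 14 lower), and the cause was not tested. With the axis score as a covariate it was 116 (100 higher, 16 lower), Il1rn among them. That score was built from the residuals of the same fit, so it cannot move the differences and makes p-values too small, and these calls are not used. All other settings gave 1, Il1rn.

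Deviations of libraries of the same number correlated at 0.26, -0.03 and -0.29, which gives no sign that the numbers pair the samples. An axis with 56.6% of the variance within groups could hide such pairing, so it is neither shown nor excluded. With the replicate block 1 of the 2 list calls was left, the reference genes. The number of lists past the threshold (2) was 0 to 1 when 1 library was left out (0 without control 1 or 2 or FHKO 2). It was 0 with medians set equal, with all reference genes set equal, after quantile normalisation, without a filter, without Hprt in the scaling, with an estimated correlation, with ranks and with fry. Fewer samples or more lists tested can lower such a count, and otherwise the cause was not tested.

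Of 69 genes followed 13 changed sign in some setting, 7 of them only with medians set equal, which lowers every gene by 0.29. With medians set equal, C3ar1 had -0.094, C1qa -0.15, C3 -0.27, Itgam -0.14, Tnf -0.11, Ctss -0.016, Cd180 -0.060, Nfkbia -0.015, Grn -0.21, Csf1r -0.030 and Adgre1 -0.18, where the median of all genes itself moved from 0.16 to -0.14. Quantile normalisation gave C3 -0.30, Tnf -0.084 and Csf3r -0.020. edgeR gave C3 -0.11, Grn -0.043 and Adgre1 -0.014, and DESeq2 gave C3 -0.12, Grn -0.054 and Adgre1 -0.024. Leaving out 1 library gave C3 -0.11 to 0.11 and Fscn1 -0.25 to 0.0038. Relative to the median gene, list means so ranged from -0.0047 to 0.051 for macrophage identity, -0.080 to 0.059 for chemokines, -0.11 to 0.030 for pro-inflammatory mediators and -0.0091 to 0.058 for lipid genes. Chemokines had 0.0093 and lysosome genes 0.024 after quantile normalisation, lipid genes -0.017 without a filter, pro-inflammatory mediators 0.041 and interferon genes -0.11 with the filter at 50, and chemokines 0.021 with the negative-control filter. Apart from the shift of medians the cause was not tested. Counts of 8.38 to 14.8 in negative controls limit what can be read from the lowest genes.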

Other observations

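The test by other splits of the libraries was planned before its result was seen. The tests of scaling, of the axis within the groups, of total count and of Hprt were chosen after the values behind them had been seen.

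Il1rn was lower in FHKO macrophages. Its adjusted p stayed under 0.05 in 6 other scalings, the largest being 0.0450 (limma, scaling without Hprt). Medians, quantiles, edgeR and DESeq2 scale by the whole panel. The panel lay above the scaling genes in FHKO, so these settings lowered Il1rn further. The others use nearly the same reference genes as the authors. The call therefore held across these scalings, which does not decide whether the authors' scaling took part in it. An axis of variation within the groups held 56.6% of the variance within groups. After its removal from each library the log2 difference of Il1rn was -0.80 with a standard error of 0.059. That standard error is too small because the axis came from the same residuals. Removal moves a gene only as far as the gene varies along the axis within groups. Il1rn had the smallest p, which favours a small spread within groups, so this test does not decide whether the axis took part. Of the 10 splits of the 6 libraries 1, the real one, gave as many genes past the threshold (1 gene, and 0 as the highest of the others, or 110 and 78 genes at an unadjusted p under 0.05), and 10 splits are too few for a share under 0.05. An effect of the missing factor H stays open as a hypothesis, as do differences between cultures or animals that the design cannot separate from genotype, and the call itself was lost when any 1 library other than FHKO 2 was left out (limma, adjusted p of 0.0632 to 0.169).

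Most genes were higher in FHKO macrophages relative to the scaling genes. Total count does not account for it, since the difference of library medians was 0.29 without and 0.28 with total count as a covariate (standard error 0.058). Neither does Hprt among the scaling genes, since without it the median difference was 0.20. The axis within the groups stays open: across genes, which are not independent replicates, control 3 minus control 1 correlated with the FHKO mean minus control 2 at a Pearson r of 0.448, between the bounds set for and against it. That value depends on the libraries: over the 6 pairs within a group, each against the group difference of the other libraries, r ranged from 0.0646 to 0.448 and was under 0.3 in 4, and a version without control 1 gave 0.0713. On the axis lay 38.9% of the squared group difference. After its removal the median difference was 0.08, from 0.16, with 65.3% of the genes above 0. The difference of library medians was 0.12, from 0.29. Of all tested genes 61.8% kept at least as much of their difference as they lost. Among the 110 genes at an unadjusted p under 0.05, which were picked for their difference, 84 did (69 of the 93 higher genes). The shift may therefore be in part a difference in state or quality between cultures, and genotype and this axis cannot be told apart for it.

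Id1 and Id3 were higher in FHKO macrophages, short of the threshold in limma (adjusted p = 0.0993) and edgeR (adjusted p = 0.0909) and called by DESeq2 (adjusted p = 0.00732). After removal of the same axis the smaller of their differences was 1.14 (Id3, from 0.96). Within FHKO, Id3 was at 242 in library 2 and at 361 and 369 in libraries 1 and 3, so that value rests largely on library 2. The axis came from the residuals of these same libraries, so its removal does not exclude it as a cause. Removal lowered the differences of Ccr2 (from 1.09 to 0.42) and Tlr4 (from 1.08 to 0.35) and left those of Nlrp3 (0.56) and Cx3cr1 (0.61) in place. A gene moves only as far as it varies along the axis within groups, so this does not decide for these genes either. With library medians set equal Nlrp3 and Cx3cr1 had 0.26 and 0.32.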
